A study of Mus musculus with 2 samples.

How the data were processed

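DNase-seq maps chromatin that the nuclease DNase I can cut, so that called regions mark accessible DNA. The libraries came from hindbrain of mouse embryos (strain B6NCrl) at embryonic day 10.5, with male and female embryos pooled, per the labels. There was 1 group with 2 biological replicates and no control. The labels give both replicates the same donor identifier and separate biosamples, so the spread between them covers separate tissue samples of that strain. With 1 group there was no test between groups, and errors are the SD over n = 2 libraries.

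All coordinates are on mm10, per the labels. Each library was called on its own, and replicates were not pooled, per the file descriptions deposited with the data. The aligner, the caller, their versions and the threshold between the peak lists are not given in the sources used here. A first analysis by the authors made a peak list of regions of up to 150 bp, a list of hotspots (wider regions of raised cutting) and a file of cut rates. Column 7 of the deposited peak list is a signal, the height of the peak, which is exactly whole (no tolerance) in 100% of peaks and is not scaled to depth. In the deposited hotspot list the authors gave a −log10 value per region and a score that is 10 times that value. Whether the −log10 value comes from a p-value or a false discovery rate is not given in the sources used here. A second analysis by the authors, from another set of filtered alignments, made 2 further peak lists with signal heights scaled to depth, a footprint list and a second cut-rate file. The footprint list carries 1 constant value throughout, so only its positions were used. The deposited cut-rate files list a false discovery rate (a p-value adjusted for the number of tests) for intervals under 0.05 and no count or signal. A total of cuts, which had been planned, could therefore not be formed, and the number of listed bases was used in its place.

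The depth of each library is not stated. The scaled heights were whole multiples of 1 step per library (100% of the 123597 and 128394 heights under 3, tolerance 0.02), which implies 213.7 M tags for replicate 1 and 202.4 M tags for replicate 2 if the unit is a height per M tags. That unit is an inference from the values.

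The first-analysis peak list was the main measure because the same analysis made the hotspots. This choice, the 18 gene lists, the 31 consensus motifs, the tests of the report, all but 3 of the alternatives and the rule for named items were fixed before the data were examined. These 3 alternatives and some tests of explanations were chosen later, as the closing section says. Regions on 21 chromosomes (1 to 19, X and Y) were kept. The annotation was GENCODE vM21 with 21829 protein-coding gene symbols, on a reference of the same build, of which 27 symbols stand for several genes. One member of the ventral list, Nkx2-8, has no symbol in it.

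Regions were called shared when they overlapped by at least 1 bp. Chance overlap came from 20 shuffles per list with bedtools 2.31.1, within chromosomes and outside assembly gaps, and within the hotspots of the library for footprints. Heights were compared over pairs of peaks that were each other's best overlap. A peak was a promoter peak when its midpoint lay within 1000 bp of a protein-coding transcription start site (TSS), and otherwise exonic, intronic or intergenic by its midpoint. A gene had a promoter peak when any peak overlapped the window of 1000 bp on either side of one of its TSSs. A peak over 2000 bp from every TSS and within 100000 bp of the nearest was counted as a distal peak of the gene with that TSS. The domain of a gene is the length of sequence from which it can draw distal peaks. Each list's mean was placed among 10000 random lists of the same size, for distal peaks matched on 20 bins of domain length. Genes of equal domain length were ordered by symbol, so they could fall in different bins. At 196 kb the mean of the bin was 7.55 distal peaks for Irx3 and 12.8 for Sox2. How far this moved the list results was not tested. Percentiles describe these libraries and are not p-values, since genes are not replicates. The permutation p-values of the list comparisons and of the Hox correlations are likewise across genes, which are not independent replicates. A list was called above random lists at the 97.5th percentile and below them at the 2.5th. The hindbrain list was set against each of 17 others by a two-sided permutation test (100000 resamples) of distal peaks minus the mean of the domain bin, with genes in both lists left out and Benjamini-Hochberg adjustment over the 17.

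For the Hox clusters, each gene was given the interval from midway to the previous Hox TSS to midway to the next (mirrored at cluster ends), and the share of it covered by peaks was correlated with paralog number across 39 genes. Footprints extended by 5 bp were scanned on both strands for each consensus, beside 1 control window of the same width per footprint at a random place in the hotspots of the library that overlapped no footprint. Where no control window held a consensus, the ratio was computed against a floor of 3 counts and is a lower bound. Binomial intervals are exact (Clopper-Pearson, 95%). Intervals and floors cover counting error only. A withheld item is not reported here.

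The named items were, by rule, the 4 genes with the most and the 2 with the fewest mean distal peaks of the 7 neural lists of progenitors, regions and hindbrain neurons, and the 2 highest and 1 lowest of the other lists. They also took in the 10 genes with the most distal peaks genome-wide, the 10 distal and 5 promoter shared peaks of greatest mean height, the 5 highest peaks of each library with no overlap in the other, and the 8 highest and 4 lowest motifs. Genes were ranked by raw distal counts, which are not scaled to domain length. Other places in the reference that match the strongest shared peaks were sought with blastn (at least 100 bp and 90% identity). The alternatives were the other peak lists, the 50% of peaks of greatest height, equal numbers of peaks, autosomes, 50% reciprocal overlap, other windows and distances, other backgrounds and controls, hotspots, either library alone, and other cut-rate files and bins.

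The list, overlap and motif steps were tested on simulated data. Of 100 simulated lists of 20 genes among 21829 genes, the percentile called 3% with no planted change, 72% with distal counts raised 2-fold and 96% with counts raised 3-fold. The permutation test, at an unadjusted p below 0.05, called 3%, 31% and 62% of them, so differences of 2-fold between lists are often missed. A planted overlap of 60.0% of 136182 peaks was measured as 61.8%. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, pysam 0.24.0, matplotlib 3.10.9 and blastn 2.17.0.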

Results

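Accessible chromatin was mapped by DNase-seq in the hindbrain of mouse embryos at embryonic day 10.5, in 2 biological replicates from pooled male and female embryos. The hindbrain is the part of the neural tube that forms the medulla, pons and cerebellum. Replicate 1 had 136182 peaks and replicate 2 had 147908 (mean 142045 ± 8292, SD, n = 2), which covered 0.781% of the genome. Hotspots numbered 110784 and 124871 and covered 58.0 and 58.5 Mb. Footprints, the short protected stretches inside accessible DNA, numbered 361618 and 415656, with a median width of 9 bp. The implied depth was 213.7 M tags for replicate 1 and 202.4 M tags for replicate 2. With 1 group there is no comparison between conditions, and the comparisons below are between replicates, genomic locations, gene lists and motifs.

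Genes with the most distal peaks included transcription factors of development and some genes with very long domains. Distal counts per gene correlated between replicates with rho = 0.909 across genes. The most distal peaks genome-wide belonged to Nr2f2 (ENSMUSG00000030551; 91 and 73 in replicates 1 and 2), an orphan nuclear receptor. Next came Bcor (70 and 67), Gse1 (55 and 78), Pax2 (62 and 68), Auts2 (61 and 68), Pde4d (66 and 59), Hand2 (58 and 61), Nav2 (55 and 63), Sox2 (67 and 51) and Zfhx3 (48 and 70). Pax2 is a transcription factor of the midbrain-hindbrain boundary, Sox2 one of neural progenitors and Hand2 one of heart and limb. Pde4d, Auts2 and Nav2 have domains of 1356, 796.7 and 471.1 kb, and these counts are not scaled to domain length.

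In the hindbrain identity list genes had 14.2 ± 0.212 distal peaks (SD, n = 2), 3.20 times random lists of matched domain length and above all of them, with 18 of 20 genes above the mean of their domain bin. The homeobox genes Irx3 (35.5 ± 2.12) and Gbx2 (30 ± 2.83), Meis2 (29.5 ± 7.78) and the ephrin receptor gene Epha4 (27.0 ± 4.24) had the most. Hoxa3, whose domain is 3.32 kb, had none, and Fgf3 had 1.5 ± 0.707. The boundary list stood at 4.80 times random lists, led by Pax2 (65.0 ± 4.24), Lmx1b (55.0 ± 7.07), En1 (36.5 ± 0.707) and Otx2 (33.5 ± 3.54). Fgf17, with a domain of 4.51 kb, had 2 in each library, and Wnt1 had 1 and 10. Fgf17 and Wnt1 were above the mean of their domain bins (0.427 and 0.713), and Hoxa3 and Fgf3 were below theirs.

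Lists of neural progenitors and neurons were also above random lists. Dorsal progenitor genes stood at 4.17 times, led by Pax3 (39 and 78), Zic4 (58.0 ± 4.24), Pax7 (49.5 ± 10.6) and Msx1 (37.0 ± 7.07), with 0 at Zic1, which has no distal domain, and 5.5 at Gdf7. Ventral progenitor genes stood at 3.87 times, led by Sim2 (35.5 ± 2.12), Foxa2 (33 in each), Pax6 (32.5 ± 0.707) and Olig2 (28.5 ± 2.12), with 1 in each library at Gli1 and 9.5 ± 6.36 at Nkx2-9. General neural progenitor genes stood at 3.64 times, from Sox2 (59.0 ± 11.3), Pou3f3 (47.5 ± 2.12), Sox1 (45.5 ± 0.707) and Hes1 (30 ± 2.83) down to Hes5 (5.5) and Fabp7 (3.0). Hindbrain neuron genes stood at 4.37 times, and all 20 were above their domain bin. Lmx1b, Barhl2 (44.0 ± 1.41), En1 and Mnx1 (35.5 ± 2.12) had the most, and Phox2a (6.0) and Fev (5.5) the fewest. The pan-neuronal list, at 1.59 times and the 97.3rd percentile, did not pass with both replicates and did with replicate 1 alone (1.66 times, 97.8th percentile), with the 50% of peaks of greatest height (2.04 times), within 50000 bp (1.77 times) and without matching on domain length (2.73 times). Its highest genes were Ebf1 and Ebf2 (27.0 ± 4.24 each) and its lowest Syt1 (0.5). Of the lowest genes of these lists, Gdf7, Gli1, Nkx2-9, Hes5, Phox2a and Fev were still above the mean of their domain bins (0.877 for Hes5). Zic1, Fabp7 and Syt1 were below theirs.

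The forebrain, neural crest, mesoderm, muscle and heart and housekeeping lists were above random lists as well. The forebrain list stood at 4.03 times random lists, with Six3 (34 and 65), Emx2 (31.5 ± 4.95), Sim1 (31.0 ± 9.90) and Lhx2 (28.5 ± 2.12) highest, and Rax (7.5) and Six6 (0, with no distal domain) lowest. Rax was above the mean of its domain bin (2.44), and Six6 was below (0.120). Neural crest genes stood at 2.91 times, from Tfap2a (55.0 ± 5.66) and Tfap2b (37.0 ± 4.24) down to Erbb3 (0.5). Mesoderm genes stood at 2.61 times, from Foxf1 (36.0 ± 4.24) and Tbx15 (29.0 ± 2.83) down to Meox2 (2.5). Muscle and heart genes stood at 2.79 times, with Tbx5 (45.5 ± 4.95) and Gata4 (34.0 ± 9.90) highest and none at Myh6, a heavy chain of cardiac myosin. Housekeeping genes stood at 2.36 times, with Ywhaz (15 in each) and Eef1a1 (10 ± 1.41) highest and 0 at Rpl13a, but at 1.19 times without matching on domain length and 1.89 times over 5000 bp from every TSS, where the list no longer passed.

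Lists of blood (1.11 times), endothelium (1.43), liver and gut (1.22), pluripotency and germline (0.881) and olfactory and keratin genes (0.686) did not stand apart from random lists. Without matching on domain length endothelium did, at 2.26 times and the 98.2nd percentile, and olfactory and keratin genes lay below, at 0.315 times. Their highest genes were Runx1 (19 in each) and Ptprc (7 in each), Flt1 (24.5 ± 2.12) and Cdh5 (13.5 ± 6.36), Cdx2 (18.5 ± 2.12) and Apob (8.5), Esrrb (23.0 ± 1.41) and Klf4 (6.5), and Krt1 (5.0) and Vmn1r1 (2 in each). Epor, Esam, Apoa1 and Flg had 0 and Ddx4 had 0.5.

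**Figure D1:**
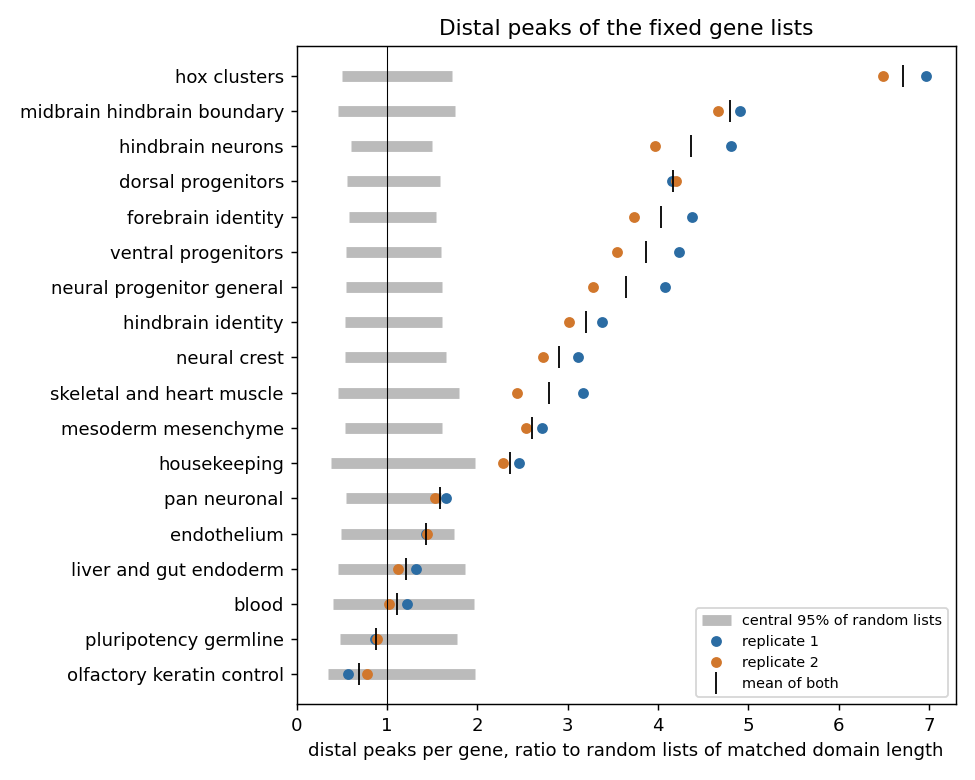
Mean distal peaks per gene of each fixed list as a ratio to random lists matched on domain length (x axis), per replicate (points) and for the mean of both (ticks), with the central 95% of random lists (grey bars). Neural lists lie from 3.20 to 4.80 except the pan-neuronal list at 1.59.

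The hindbrain list had a larger excess of distal peaks per gene than the blood, liver and gut, pluripotency and germline, olfactory and keratin and housekeeping lists. The excess is the count minus the mean of the domain bin, a difference and not a ratio. The order by ratio to random lists can differ, as the Hox list stood at 6.72 times and the hindbrain list at 3.20. Differences from the mesoderm and the muscle and heart lists did not pass, and lower values than 4 neural lists did not hold under every alternative. Each of the 17 other lists was set against it, with adjusted two-sided permutation p-values. These p-values are across genes, which are not independent replicates, and 9 genes of the hindbrain list are Hox genes that lie in clusters. The hindbrain list minus the blood list was 9.43 peaks per gene (adjusted permutation p = 0.00312), minus pluripotency and germline 10.3 (permutation p = 0.00312), minus olfactory and keratin 10.2 (permutation p = 0.00312), minus liver and gut 8.88 (permutation p = 0.0115) and minus housekeeping 7.39 (permutation p = 0.00863). These 5 differences passed under every alternative run. The differences from endothelium, 7.38 (permutation p = 0.0315), and from the pan-neuronal list, 6.27 (permutation p = 0.0404), did not pass with hotspots in place of peaks, over 5000 bp from every TSS or without matching on domain length. The pan-neuronal one also did not pass with replicate 1 alone, the smaller second-analysis list, the 50% of peaks of greatest height or within 50000 bp.

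The hindbrain list minus the boundary list was −10.8 (adjusted permutation p = 0.0398), minus dorsal progenitors −9.50 (permutation p = 0.0404), minus ventral progenitors −7.23 (permutation p = 0.0389) and minus hindbrain neurons −8.66 (permutation p = 0.0315). These 4 differences did not all hold under other choices. The 9 Hox genes of the list have a median domain of 6.99 kb and 7.78 distal peaks on average, against 115.8 kb and 19.5 for its 11 other genes. Without them 0 of the 4 passed, with 11 genes left in the list and differences of −8.21, −6.92, −4.65 and −6.08, so the loss of the calls does not show that these genes made the differences. The number was also 0 with hotspots or with the 50% of peaks of greatest height. It was 2 without matching on domain length, and hindbrain neurons did not pass over 5000 bp from every TSS. With replicate 1 alone the boundary and dorsal differences no longer passed, and with replicate 2 alone those from ventral progenitors and hindbrain neurons no longer did. The differences from forebrain (−6.25, adjusted permutation p = 0.0552), neural progenitors (−6.43, permutation p = 0.139) and neural crest (−1.22, permutation p = 0.809) did not pass. Nor did those from mesoderm (−0.756, permutation p = 0.809), muscle and heart (3.92, permutation p = 0.319) and the Hox list (6.95, permutation p = 0.0865). The forebrain difference did pass with the larger (adjusted permutation p = 0.0475) and smaller (permutation p = 0.0235) second-analysis lists and within 50000 bp (permutation p = 0.00802). With genes in both lists left out, the Hox comparison set the 11 non-Hox genes of the hindbrain list against 30 Hox genes outside it. It therefore does not compare the Hox genes of the hindbrain list with other Hox genes. This difference passed with the 50% of peaks of greatest height (permutation p = 0.0327), without matching on domain length (permutation p = 0.0122) and with hotspots (permutation p = 0.0220).

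Most promoters of the neural lists held a peak, and most of those of blood, liver and gut, and olfactory and keratin genes did not. Of 21829 genes, 14799 (67.8%) had a promoter peak in both libraries. All genes of the forebrain (18), dorsal progenitor (16), neural progenitor (16), hindbrain neuron (20), pan-neuronal (17) and housekeeping (16) lists had one. So did 18 of 20 hindbrain identity genes, 11 of 12 genes of the midbrain-hindbrain boundary, 14 of 15 ventral progenitor genes, 13 of 14 neural crest genes and 13 of 14 mesoderm genes. Promoter peaks were found for 8 of 12 endothelial, 8 of 14 muscle and heart, 5 of 14 blood, 5 of 12 pluripotency and germline, 4 of 12 liver and gut and 1 of 12 olfactory and keratin genes. Of the 39 Hox genes, 23 had one in both libraries. In all, 10 lists lay above random lists, and the blood, liver and gut and olfactory and keratin lists lay below, at the 0.7, 1.05 and 0 percentiles. Matched on promoter CpG content, 1 list remained above random lists, the pan-neuronal one at the 99.98th percentile, and the Hox and the pluripotency and germline lists then lay below matched lists. The blood list, at the 19.6th percentile, was then no longer below, nor was it with hotspots (2.9th percentile), where the liver and gut list (3.49th) was not below either. The hindbrain list was not above random lists in the larger (95.1st percentile) and smaller (90.7th) second-analysis lists or with a 500 bp window (96.2nd), mesoderm was not with that window (93.6th), and neural crest was not with a peak in either library (97.0th). The boundary list was above with the 50% of peaks of greatest height (97.7th). Muscle and heart lay below in the smaller second-analysis list (0.32nd) and with the 500 bp window (1.16th), Hox in that list (0.22nd), and pluripotency and germline in it (1.45th) and with the 50% of peaks of greatest height (1.57th). The side of the random mean turned for 4 lists with 1 replicate: with replicate 2 alone muscle and heart stood at 85.7%, pluripotency and germline at 75% and Hox at 84.6% (98.17th percentile), and with replicate 1 alone endothelium stood at 75%.

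**Figure D2:**
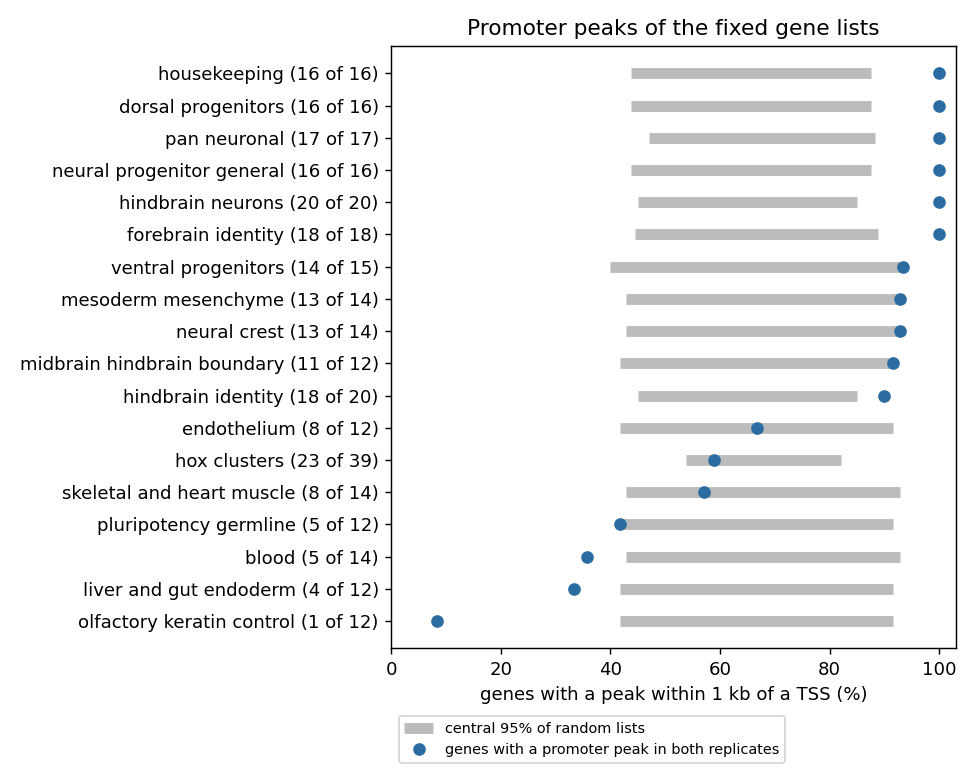
Share of genes in each fixed list with a peak within 1 kb of a TSS in both replicates (points, x axis in percent), with the central 95% of 10000 random lists of the same size (grey bars). The 6 lists at 100% lie right of their bars, and the olfactory and keratin list lies at 8.33%.

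The Hox clusters were examined because anterior paralogs are the ones used in hindbrain. Peaks covered 11.05% ± 1.40 of the intervals of paralogs 1 to 4 (SD, n = 2) and 9.17% ± 1.30 of those of paralogs 9 to 13. At paralogs 5 to 8 the replicates differed widely, with 2.32% covered in replicate 1 and 10.999% in replicate 2. Paralogs 9 to 13 differed as well within clusters, with 3.30% and 18.98% in Hoxd, 5.77% and 12.5% in Hoxc and, in the other direction, 12.2% and 6.80% in Hoxb. No relation of coverage with paralog number was found across the 39 genes pooled (Spearman's rho = −0.01, permutation p = 0.947, and Pearson's r = −0.05, permutation p = 0.765, with adjusted values of 0.947 and 0.918 over 6 relations). Single clusters went different ways, with rho of −0.38 in Hoxa (11 genes), 0.03 in Hoxb (10), 0.65 in Hoxc (9) and 0 in Hoxd (9), and were not tested singly. The sign of rho differed between replicates, at −0.10 in replicate 1 and 0.11 in replicate 2. Hoxa2 (12.9% and 19.97%) and Hoxb2 (19.1% and 16.7%) were covered in both libraries. Hoxa5 had 0 peaks in replicate 1 and 7 in replicate 2, and Hoxd4 had 1 and 23. The list stood at 6.72 times random lists in distal peaks, with Hoxb13 (58 and 26) and Hoxc4 (38.0 ± 2.83) highest and 0 at Hoxa10. Hoxb13 and Hoxc4 each lie at an end of their cluster, with domains of 64.6 and 71.8 kb, against 4.18 kb for Hoxa10.

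The consensus sites of REST, CTCF and NRF1 had the highest ratios of footprints to control windows. In both libraries 13 of 31 consensus motifs were at least 1.5 times as frequent in footprints as in control windows. The site of CTCF, an architectural protein (CCASYAGRKGGC), lay in 1.37% ± 0.0729 of footprints, 79.2 ± 0.236 times its share of controls. The counting error was wider than this SD: with 65 and 69 control windows the 95% intervals were 61.9 to 102.5 and 62.6 to 102.1. The site of REST, a repressor of neuronal genes outside neurons (TTCAGCACCNNGGACAG), lay in 128 footprints and 0 controls of replicate 1, at least 42.7-fold higher against a floor of 3 counts. In replicate 2 it lay in 144 footprints and 1 control window (ratio 144, 95% interval 25.4 to 5727). NRF1 followed at 31.6 ± 7.05, RFX at 14.7 ± 1.78, CREB at 14.2 ± 2.12, YY1 at 9.97 ± 0.744, ETS at 9.14 ± 1.28 and SP and KLF factors at 8.54 ± 0.626. The size and order of these ratios depended on the windows. With controls 100 bp downstream REST stood at 64 and 48 (2 and 3 control windows, 95% intervals 17.4 to 534.2 and 16.1 to 235.5), CTCF at 31.3 and 23.4, RFX at 6.12 and 6.84, NRF1 at 3.29 and 2.88, CREB at 3.04 and 2.72, SP and KLF factors at 2.61 and 2.66, YY1 at 2.42 and 2.19 and ETS at 2.25 and 2.33. Without flanks CTCF stood at 337.4 and 381.2.

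Other sites stood lower. The GLI site, which reads Sonic hedgehog signalling, stood at 1.85 ± 0.408, the ZIC site at 1.66 ± 0.00858, the MEIS and PBX site at 1.72 ± 0.397 and the E-box CAGCTG at 1.51 ± 0.261. The last pair of motifs was under 1.5 in replicate 1. The DR1 site of nuclear receptors, next after the 8 above, stood at 7.32 ± 1.26, and the retinoic acid receptor site DR5 at 3.15 ± 1.81, with 95% intervals of 0.746 to 5.11 and 1.91 to 11.9. NFI stood at 3.71 ± 1.36 from 11 and 14 footprints against 4 and 3 controls, with 95% intervals of 0.815 to 11.8 and 1.30 to 25.3. SOX stood at 1.19 ± 0.230 and NFY at 1.099 ± 0.0560, and NFY at 1.04 and 0.942 with controls 100 bp downstream. GATA (0.388 ± 0.0310), P53 (0.416 ± 0.0241), PBX and HOX (0.520 ± 0.0927) and PU1 (0.628 ± 0.0847) were the lowest. A further 9 motifs lay between 0.629 and 0.847, and HNF1 was found in 0 footprints and 0 controls. Footprints were richer in GC (59.9% and 61.1%) than controls (52.2% and 53.4%). Controls matched on GC came closer, at 57.04% in replicate 1 and 58.24% in replicate 2, but stayed below the footprints. The matching thus left a part of the GC difference in place. With controls matched on GC, ZIC (1.25 and 1.24) and DR5 (1.36 and 1.94) no longer reached 1.5 in both libraries, and MEIS and PBX (2.19 and 2.20) and the homeodomain site (1.81 and 1.83) did. GLI and ZIC did not reach it with a flank of 10 bp. With the GC-matched controls the mean ratio of 7 of 30 motifs moved from below to above 1: PBX and HOX to 1.21, the homeodomain site TAATTA from 0.650 to 1.82, POU octamer to 1.23, MEF2 to 1.29, SRF to 1.26, TCF and LEF to 1.09 (0.933 in replicate 1 and 1.25 in replicate 2) and the E-box CATATG to 1.18.

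**Figure D3:**
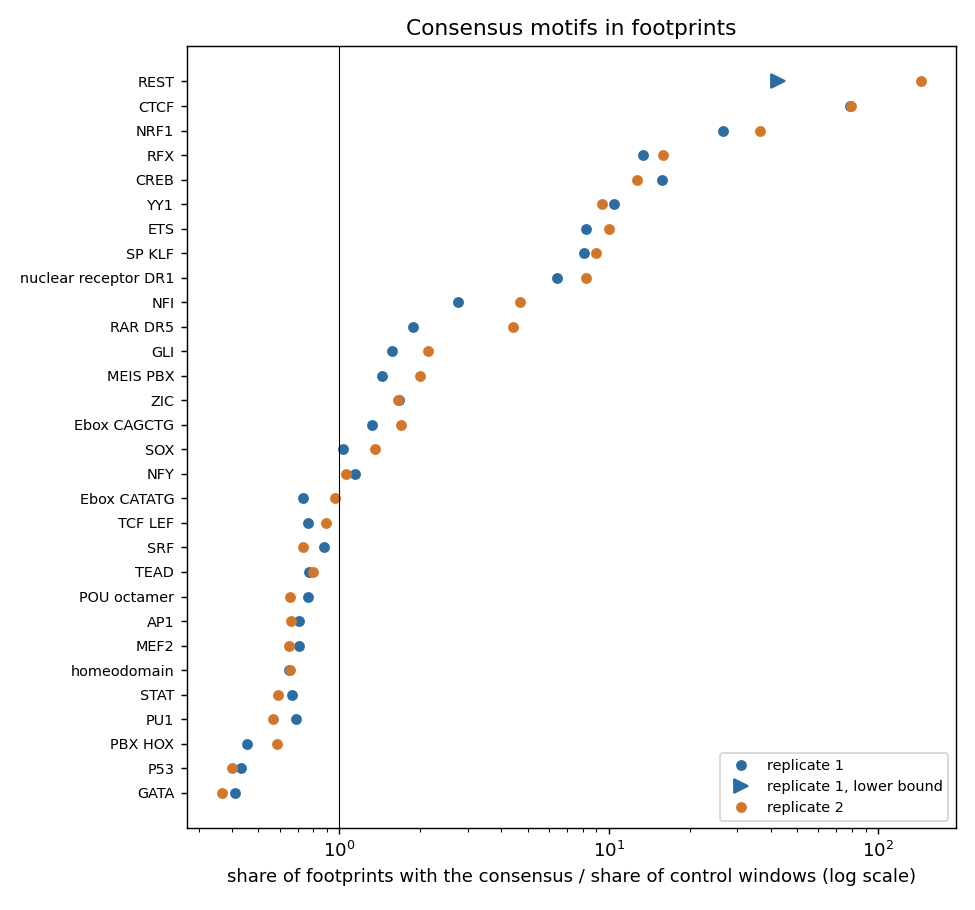
Ratio of the share of footprints with each consensus to the share of control windows (x axis, log scale), per replicate. Circles are ratios, the triangle is a lower bound for REST in replicate 1, and CTCF lies at 79.0 and 79.3. With controls matched on GC the mean of both replicates moves from below to above 1 for 7 motifs. Of these, TCF and LEF stay below 1 in replicate 1. The matched controls still lie below the footprints in GC.

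Peaks were concentrated at promoters. Promoters held 22.1% ± 1.37 of peaks (SD, n = 2), 8.45 ± 0.559 times the shuffled share. Exons held 6.89% ± 0.253, or 1.56 times the shuffled share. Introns with 36.4% ± 0.897 and intergenic sequence with 34.5% ± 0.224 held 0.869 and 0.677 times their shuffled shares. The promoter share depended on the peaks taken, at 34.8% in the 50% of peaks of greatest height and 15.8% with a window of 500 bp.

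The highest promoter peak shared by both libraries lay at chromosome 1, 88277536 to 88277685, 22 bp from a TSS of Hjurp (ENSMUSG00000044783), which encodes a chaperone of centromeric histone. Its height was 3690 in replicate 1 and 7949 in replicate 2. The promoter peaks of Myo10, Snrnp70, Nup153 and Fzr1 followed, with mean heights from 2739 down to 2668. The highest distal peak lay between genes at chromosome X, 143482976 to 143483125, 35540 bp from Pak3, with a mean height of 9930.5 ± 2587 (SD, n = 2). That sequence has 6 other matches of at least 100 bp and 90% identity in the reference, the closest on chromosome 6 at 97.1%. Exon and intron classes rest on all annotated genes, and the gene named is that of the nearest protein-coding TSS. An exonic peak 16715 bp from a TSS of Limd1, at chromosome 9, 123461916 to 123462065 (3158 and 6453), has 6 such matches. An intronic peak 28940 bp from a TSS of Jarid2, at chromosome 13, 44869556 to 44869705 (1385 and 3760), has 5. How reads with several matches were treated at these 3 places is not given in the sources used here. The other 7 distal peaks, nearest to Cd209a, Zfp395, Ptma, Socs3, Nacc2, Nemf and Tex44, had no such match, and their mean heights ran from 3113 to 2082. All 15 except the one near Pak3 were higher in replicate 2.

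Most peaks of either replicate were found in the other. Of the peaks of replicate 1, 70.2% overlapped a peak of replicate 2 (95% interval 69.9 to 70.4%), against 1.75% of shuffled peaks. In the other direction the share was 63.9% (63.6 to 64.1%), against 1.57%. Hotspots overlapped in 75.3% and 67.6% of cases, 16.8 and 17.1 times the shuffled share. Footprints overlapped in 48.0% and 39.9%, which was 3.52 and 3.27 times the share of footprints shuffled within hotspots. Sharing followed height: of the 25% of peaks of greatest height 94.8% and 94.9% were shared, and of the 25% of least height 36.3% and 29.0%. Under 50% reciprocal overlap the mean share was 29.7% for footprints, 58.8% for peaks and 52.9% for hotspots. Footprints had a median width of 9 bp against 150 bp for peaks, so a shift of a few bp can end their overlap. The lower share therefore does not measure repeatability on the same terms.

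Across 93013 shared peaks the log10 heights correlated with Pearson's r = 0.955 and Spearman's rho = 0.940, across peaks, which are not independent replicates. Counting peaks absent from 1 library at the lowest rank, the correlation was 0.685. Peaks were higher in replicate 2, by a median of 0.62 on the log2 scale (1.54-fold, SD 0.44 across peaks). The ratio was 1.66 at promoters and 1.48 between genes. Bases listed under the cut-rate threshold spanned 56.8 and 57.6 Mb, of which 80.4% and 79.3% were listed in both libraries. Over 10 kb bins the listed bases correlated with r = 0.933.

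Peaks with no overlap in the other library were mostly low, with median heights of 52 and 67 against 116 and 176 for shared peaks. The 5 highest of replicate 1 lay at promoters of Gpbp1, Rnf44, Rab8a, Prmt1 and Acadm, with heights from 1255 to 971. Those of replicate 2 lay at promoters of Prmt1, Napa, Ssbp2, Prr11 and Ppp2r1a, with heights from 2273 to 1900. All 10 lay inside a hotspot of the other library. At Prmt1 the peaks of the 2 libraries were placed at 44986416 to 44986565 and 44986576 to 44986725 on chromosome 7, side by side. Of all peaks found in 1 library, 29.4% and 22.0% lay in a hotspot of the other.

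The X chromosome held 2.94% of peaks in replicate 1 (95% interval 2.85 to 3.03%) and 2.72% in replicate 2 (2.63 to 2.80%). The Y chromosome held 42 peaks (0.0308%, 0.0222 to 0.0417%) and 58 peaks (0.0392%, 0.0298 to 0.0507%). The intervals of the replicates overlapped for Y and did not for X. The X had 23.4 and 23.5 peaks per Mb against 53.7 and 58.4 on autosomes.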

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

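In the Hox pattern all 3 tests were chosen after the result was seen, as were the tests of heart genes and of sequencing depth; those of hotspots, low CpG and GC content were written before.

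Some peaks of the larger second-analysis lists lay outside the peaks and hotspots of the first analysis. Of these, 43 of replicate 1 and 44 of replicate 2 were found in both libraries. They lie outside the main measurement, and their list enters the report only as an alternative. Outside the first analysis lay 3790 peaks of replicate 1 (2.92%) and 2495 of replicate 2 (1.74%). Those found in both libraries are 1.13% and 1.76% of them. Median heights of all peaks outside the first analysis were 0.257 and 0.306, against 0.435 and 0.588 for all peaks.

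Paralogs 5 to 8 of the Hox clusters held few peaks in replicate 1, as did paralogs 9 to 13 of Hoxd, which were not tested singly. Replicate 1 held 19.7% of the 76 replicate 2 peaks at paralogs 5 to 8, which restates the pattern. Of replicate 2 peaks of the same height elsewhere it held 85.4% (77.6 to 92.1%), so at that height replicate 1 found most peaks. The group was picked for this gap, so the difference between these shares is no test of a lower sensitivity across the genome. A second candidate is the local background of the caller, under which tall peaks would carry a weak −log10 value. The first test of it took in peaks of all Hox genes and spoke against it, with median percentiles of 80.2 and 61.0 among peaks of the same height. That test was wider than the pattern. Over paralogs 5 to 8 alone, a split made after seeing it, the medians were 0.038 and 2.91, on 16 and 75 peaks. The −log10 values were thus weak for the height of the peaks in both replicates, as under a local background. Since replicate 2 held peaks there all the same, the split does not decide what set replicate 1 apart. No biological explanation was tested.

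The forebrain, muscle and heart and neural crest lists, led by Six3, Tbx5 and Tfap2a, were above random lists in distal peaks. The blood, liver and gut and pluripotency and germline lists, at 1.11, 1.22 and 0.881 times, were not. Tiling of wide regions by 150 bp peaks as the whole cause is argued against by counts of hotspots. With these the forebrain list stayed at 2.76 times random lists or more. In replicates 1 and 2 neural crest stood at 2.32 and 2.47, and muscle and heart at 2.26 and 1.95 (99.38th percentile in replicate 2). The forebrain ratio fell from 4.38 and 3.73 to 2.93 and 2.76, so a part stays open. CpG-rich sequence as the whole cause is argued against for the forebrain list, since low-CpG distal peaks alone gave 3.12 and 2.72, at the 100th percentile. These ratios lay below the 4.38 and 3.73 of all distal peaks, so a part stays open here too. In replicate 2 neural crest stood at 2.04, and muscle and heart at 1.89, at the 97.9th percentile and only just past the threshold. Heart cells in the dissection stay open, because 3 of 6 structural heart genes (Myl7, with heights of 85 and 113, Myh7 with 81 and 124, and Actc1 with 47 and 72) had a promoter peak in both libraries while Tnnt2 (55) and Nppa (80) had one in replicate 2 alone and Myh6 in neither, which does not decide either way. No biological explanation was tested, as the design holds 1 tissue.

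Peaks were higher in replicate 2, most of all at promoters. The implied tags of replicate 2 were 0.947 times those of replicate 1. This does not decide on depth as the cause of the ratio over all peaks. They come from the second analysis, with other alignments and an inferred unit, and the depth behind the first-analysis heights was not measured. The depth-scaled heights of the larger second-analysis list also had a higher median in replicate 2 (0.588) than in replicate 1 (0.435). For the larger ratio at promoters GC content is a candidate cause: the difference between promoters and intergenic peaks was 0.16 on the log2 scale, and 0.0256 (bootstrap interval 0.0120 to 0.0397) within bins of equal GC. What raised the heights over all peaks stays open.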

How the results depend on the processing

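The hindbrain list without its Hox genes, counting peaks found in both libraries, and hotspots for promoters were chosen after seeing the data; all other alternatives were planned. The number of lists above random lists in distal peaks stayed between 11 and 13 (12 as reported) and that of enriched motifs between 12 and 15 (13 as reported), though the motifs counted changed, as 2 left and 2 entered with GC-matched controls, and the shares of X and Y moved by less than the spread between replicates under each alternative run. Where the cause of a shift is not named below, the cause was not tested. The smaller second-analysis list held 86049 peaks on average. The mean shared share of peaks was 72.3% in the larger and 78.5% in the smaller second-analysis list, 81.0% in the 50% of greatest height and 58.8% under 50% reciprocal overlap, which gave 52.9% for hotspots and 29.7% for footprints. The correlation of heights was 0.956 in the larger second-analysis list, 0.949 in the 50% of greatest height and 0.685 with absent peaks at the lowest rank, and that of cut rates was 0.948 in 100 kb bins. In the smaller second-analysis list promoters, introns and intergenic sequence held 31.2%, 31.5% and 30.2% of peaks. In the 50% of greatest height promoters, exons, introns and intergenic sequence held 34.8%, 7.32%, 30.1% and 27.7%, and with a 500 bp window 15.8%, 8.31%, 39.96% and 35.9%. Equal numbers of peaks put 33.7% between genes. Matched on promoter CpG, 1 list lay above random lists in promoter peaks, and the lists below numbered 6 in the smaller second-analysis list and 1 with hotspots. Shares that had not passed crossed the mean of random lists with a peak in either library. Endothelium stood at 75%, muscle and heart at 85.7%, pluripotency at 75% and Hox at 89.7% (99.8th percentile, above random lists). Muscle and heart also crossed it, at 57.1%, when CpG-matched. With 1 replicate left out in turn, endothelium ranged over 66.7 to 75% and muscle and heart over 57.1 to 85.7%. Pluripotency then ranged over 41.7 to 75% and Hox over 64.1 to 84.6%. The distal ratio of blood was 0.919 over 5 kb and 0.912 without domain matching, and that of pluripotency 1.26 without matching. The lists that differed from the hindbrain list numbered 11 as reported, 7 in the 50% of greatest height, 6 with hotspots and 7 without its Hox genes. Those above it, 4 as reported, numbered 0 in the 50% of greatest height, with hotspots and without Hox genes, 2 without domain matching and 2 with either replicate left out. The hindbrain list exceeded neural crest by 1.16 in the 50% of greatest height and 1.36 without Hox genes, and mesoderm by 0.204 with hotspots and 1.82 without Hox genes, none past the threshold. The Spearman correlation of Hox coverage with paralog number lay between −0.10 and 0.11 when a replicate was left out. The PBX and HOX ratio was 1.21 with GC-matched controls. Of 729 values of named genes under all distal alternatives pooled, 385 moved by at least the SD between replicates. Alternatives that take fewer peaks or a narrower range of distances lower counts by construction. A gene with equal counts in both replicates has no spread and counts as moved whatever the change. The number therefore does not show which choice moved the counts of single genes. With 2 libraries the spread itself is poorly known.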
